A study of Rattus norvegicus with 12 samples.

How the data were processed

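Gene expression was measured in 12 samples of rat spinal cord RNA, 3 pools for each of 4 groups. Per the labels' protocols, total RNA was purified with DNase treatment, amplified and labelled with Cy3, and 1 array was hybridised per pool. The pools came from separate animals, and pooling averages the rats within each, so limma p-values here rest on the spread between pools. Permutation p-values over probe pairs take the pairs as units and hold no spread between pools. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 12.0.3.1, whereas the submitters' processing notes name version 10.7 and limma. The processed intensity deposited by the authors is background-subtracted and detrended within the array and not normalized between arrays. The authors also deposited a table of log2 values with 1 column per array, whose column medians ran from 6.74 to 6.75. Its values differed by a median of 0.00975 from quantile-normalized log2 processed intensities computed here, and each column correlated best with its own array (lowest r 0.997), so that its scale is log2 and it is not centred per probe. The exact steps that made it are not given in the sources used here, and it served as an alternative only.

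The arrays held 61657 spots of 45751 different probes, 15906 of them spotted 2 times, besides 1319 control spots, which were left out. No spot was saturated. Between 0 and 10 spots per array carried an outlier flag and were left out. The median SD of duplicate spots on an array lay between 0.06 and 0.08 on the log2 scale. Each array's log2 processed intensity was set relative to its 75th percentile over all non-control spots, since over 66% of spots were well above background on every array, and the spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group. Of the 45751 probes, 11299 were not, and 13 more had a missing value after flagged spots were removed, which left 34439. No arrays held identical values.

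Comparisons were made with limma 3.58.1 in R 4.3.3: a single fit of 4 group means to all 12 arrays, contrasts of 2 h, 2 d and 7 d with control, of 2 d with 2 h and of 7 d with 2 d, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment within each comparison with a threshold of 0.05. The groups, the comparisons, most of the alternative fits and the rule for named items were fixed before the data were examined. Added later were the fits without the pools that stood apart, 2 d against 2 h within slide 2, the shared calls, courses and opposite-sign sets with the slide as a block, the tests of the pools, the slide estimate against single pools and the permutation p-values. That rule took called probes whose 3 arrays of a group did not overlap those of the other, in order of log2 fold change, and required a gene symbol. The files hold no symbols: for all 45751 probes the gene name repeats the probe number, the description reads unknown and no coordinate is given. None of the probe numbers could be matched to the table of rat genes supplied with the files. The symbol condition was therefore dropped, the number of items was limited to 2 rises and 2 falls per comparison, and a named probe had to be well above background on all arrays of both groups, since values near background have no order. For the same reason the planned counts of noncoding genes, the shifts of 33 gene lists and the choice among probes of a gene were not made, and the unit throughout is the probe. Several probes can measure a single transcript. Where a probe was not well above background on any array of a group, its fold change is a lower bound: the mean of the brighter group against, per array, the higher of the probe's own signal and the lowest signal of a probe well above background.

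The fit was tested on simulated arrays with the control means, the variances of the fit and 200 changed probes among 34439. Simulations for 2 h, 2 d and 7 d against control used the same means and variances and differed only by random draw. They recovered 61%, 72% and 70% of 2-fold changes and 32%, 35% and 50% of 1.5-fold changes. The unchanged probes called numbered 8, 3 and 5. Far more probes were called in the measured comparisons, which makes the adjustment there less strict. The recovered shares are therefore not the sensitivity of those comparisons. The search for sequence motifs ranked 10 of 10 planted motifs first, and the search for overlapping probes found 50 of 50 planted pairs on either strand. Motif shifts were means of log2 fold changes, limited to 4 in size, after removal of differences between classes of GC content and 20 classes of mean level. Correlations over probe pairs were compared with 100000 random re-pairings.

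Alternatives covered the background correction (normexp with offset 50), quantile normalization, other centring, the authors' log2 table, filters on dim probes, outlier flags, the arrays in the fit, the variance trend, the slide as a fixed or random block and within slides, the replicate number as a block, each pool left out in turn, and stricter thresholds. The normexp correction was always run together with quantile normalization. Sequence work used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.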

Results

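RNA from the spinal cord of female rats was hybridised to single-colour Agilent oligonucleotide arrays after a contusion injury, in which a 10 g weight fell from 50 mm onto the cord exposed at thoracic vertebra 10. Animals of the control group had the laminectomy, the removal of the overlying vertebral arch, without the contusion. Cord was taken 2 h, 2 d or 7 d after injury. Each of the 4 groups had 9 rats, combined into 3 pools of 3 rats with 1 array per pool, so that the 12 arrays covered 36 rats and the spread between arrays is a spread between pools. The arrays carried 45751 different 60-nt probes of the design for messenger and long noncoding RNA. The files identify these probes by serial number and sequence and do not pair them with gene names, so the comparisons below are of probes, a few of which are identified by number and sequence. Between 66.2% and 81.4% of the spots of an array were well above background, and 34439 probes were well above background on all 3 arrays of at least 1 group and entered the tests. Levels are log2 signals relative to the 75th percentile of the same array, given as mean ± SD with n = 3 pools, and the number of pools limits their precision.

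The 12 pools separated by group. The first principal component, which carried 68.1% of the variance, placed the control and 2 h pools on one side and the 2 d and 7 d pools on the other, and the second, with 14.3%, parted 2 h from control. Correlations across probes lay between 0.994 and 0.996 among control pools, between 0.962 and 0.976 for control against 2 h, and between 0.885 and 0.937 for control against 7 d. The median SD of a probe between pools was 0.09 in control, 0.15 at 2 h, 0.13 at 2 d and 0.17 at 7 d. Pool 1 at 2 d and pool 2 at 7 d lay farther along the first component, at 98.5 and 137, than the other pools of their groups, which lay between 64.2 and 77.5. The arrays came from 2 slides. Slide 1 held all control pools and 2 h pools 1 and 2, and slide 2 held 2 h pool 3 and all 2 d and 7 d pools, so that comparisons of 2 d and 7 d with control cross the slides and are linked only through the 2 h group.

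**Figure D1:**
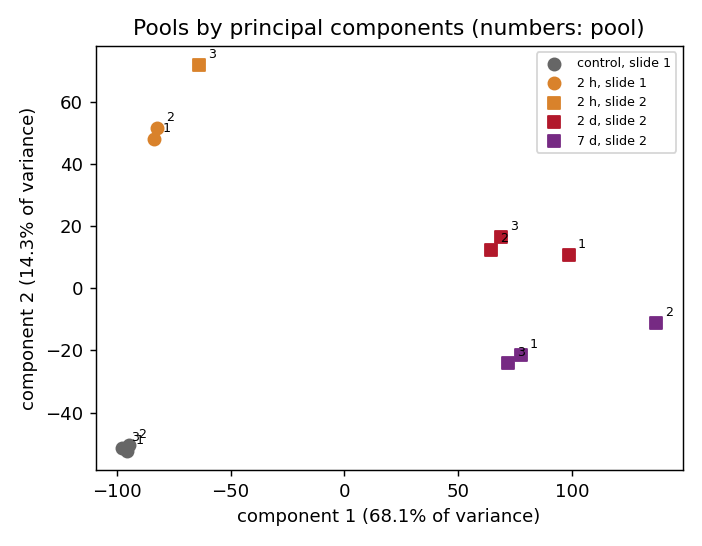
Position of each pool on the first principal component (x axis, 68.1% of variance) and the second (y axis, 14.3% of variance) of the log2 levels of 34439 probes, with colour for group, marker shape for slide and the pool number beside each point. Control and 2 h pools lie at negative values of the first component, and 2 d and 7 d pools between 64.2 and 137.

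The first question was which transcripts had changed 2 h after the contusion. Against control, 4457 probes were higher and 4318 lower at an adjusted p under 0.05, which together made 25.5% of the probes tested. Large changes were mostly rises: 1438 probes rose and 524 fell by at least 2-fold, and 186 rose but 12 fell by at least 8-fold. Among probes measured on every array of both groups, RATLNCRNA_22577 (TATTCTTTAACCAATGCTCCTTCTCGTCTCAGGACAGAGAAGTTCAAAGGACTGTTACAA) rose most, from -4.60 ± 0.29 (SD, n = 3) in control to 5.20 ± 0.46 at 2 h, a log2 fold change of 9.80 (SE 0.25) or 890-fold with a limma adjusted p of 7.84e-10. It was still 5.89 above control at 2 d and 5.03 above control at 7 d on the log2 scale. RATLNCRNA_9085 (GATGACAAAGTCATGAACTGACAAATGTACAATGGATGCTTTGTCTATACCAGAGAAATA) rose 173-fold, from -3.40 ± 0.78 to 4.03 ± 0.19 (log2 fold change 7.44, SE 0.30, limma adjusted p = 1.27e-08). The deepest falls were those of RATLNCRNA_9910 (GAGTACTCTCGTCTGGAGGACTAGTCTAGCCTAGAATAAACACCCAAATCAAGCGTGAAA), from 0.76 ± 0.36 to -2.95 ± 0.23 (log2 fold change -3.71, SE 0.25, limma adjusted p = 6.44e-07), and RATLNCRNA_18459 (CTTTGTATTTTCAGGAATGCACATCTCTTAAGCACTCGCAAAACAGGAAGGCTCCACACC), from -0.20 ± 0.39 to -3.81 ± 0.08 (log2 fold change -3.61, SE 0.25, limma adjusted p = 1.03e-06). After background correction with normexp and an offset, together with quantile normalization, the log2 fold changes of these 4 probes were 8.17, 6.38, -3.06 and -2.59. A further 78 probes were well above background in all 2 h pools and in no control pool, and 71 of them were called higher with a rise of at least 2-fold against the lowest measurable control signal. The reverse pattern held for 90 probes, of which 60 were called lower, 15 of them with a fall of at least 2-fold by the same bound. With the slide as a block, 3916 probes were higher and 3348 lower, and within slide 1, with 2 h pools 1 and 2 only, 5890 were higher and 7365 lower. Both settings leave 2 h pool 3 out of the fold changes and differ only in the error, so they are not separate checks. Centred on the median of each array instead, 3816 probes were higher and 5385 lower, so the directions cannot be ranked by their counts. The count of lower probes fell to 2691 without control pool 1 and to 2864 without control pool 2.

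At 2 d after injury more probes differed from control than at 2 h, by a number that depends on how the slides are treated. Against control, 10766 probes were higher and 10883 lower, 62.9% of those tested, or 6069 and 5144 with the slide as a block, and 4044 rose and 3869 fell by at least 2-fold. Changes of at least 8-fold were again mostly rises, with 529 probes at least 8-fold higher and 44 at least 8-fold lower. RATLNCRNA_14623 (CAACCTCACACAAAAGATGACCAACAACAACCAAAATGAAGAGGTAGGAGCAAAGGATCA) went from -4.42 ± 0.05 (SD, n = 3) in control to 3.30 ± 0.16, a 212-fold rise (log2 fold change 7.73, SE 0.16, limma adjusted p = 1.62e-10). RATLNCRNA_23424 (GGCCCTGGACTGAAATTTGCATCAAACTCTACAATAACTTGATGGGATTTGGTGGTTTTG) rose 142-fold, from -4.64 ± 0.36 to 2.51 ± 0.59 (log2 fold change 7.15, SE 0.25, limma adjusted p = 5.09e-09). In the other direction, RATLNCRNA_37365 (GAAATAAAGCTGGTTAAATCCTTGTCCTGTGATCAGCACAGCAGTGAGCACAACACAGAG) stood at 1.24 ± 0.09 in control, 1.19 ± 0.13 at 2 h and -3.26 ± 0.11 at 2 d, a log2 fold change from control to 2 d of -4.49 (SE 0.30, limma adjusted p = 3.21e-07). RATLNCRNA_18377 (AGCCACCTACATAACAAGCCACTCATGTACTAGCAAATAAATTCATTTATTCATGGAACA) went from 0.16 ± 0.12 to -3.75 ± 0.39 (log2 fold change -3.91, SE 0.49, limma adjusted p = 3.47e-05; -3.32 with the slide as a block, limma adjusted p = 0.0199). The normexp correction with quantile normalization gave 6.11, 5.45, -3.61 and -2.82 for these 4 probes. There were 236 probes well above background in all 2 d pools and in no control pool, all of them called higher and 228 with a rise of at least 2-fold by the bound, and 663 with the reverse pattern, of which 505 were called lower and 174 with a fall of at least 2-fold by the bound. All control pools were on slide 1 and all 2 d pools on slide 2. Under the slide block, 5528 of the 7913 probes that had changed at least 2-fold (69.9%) were still called in the same direction. The block estimates the slide difference from the 2 h pools, with 2 h pool 3 alone on slide 2. This widens the error of 2 d against control even without a slide difference. RATLNCRNA_14623 had a larger log2 fold change under the block, 8.12, but a higher limma adjusted p of 3.22e-07. A call lost under the block is thus by itself no sign of a slide difference. No slide held both groups, so no value within a slide exists.

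**Figure D2:**
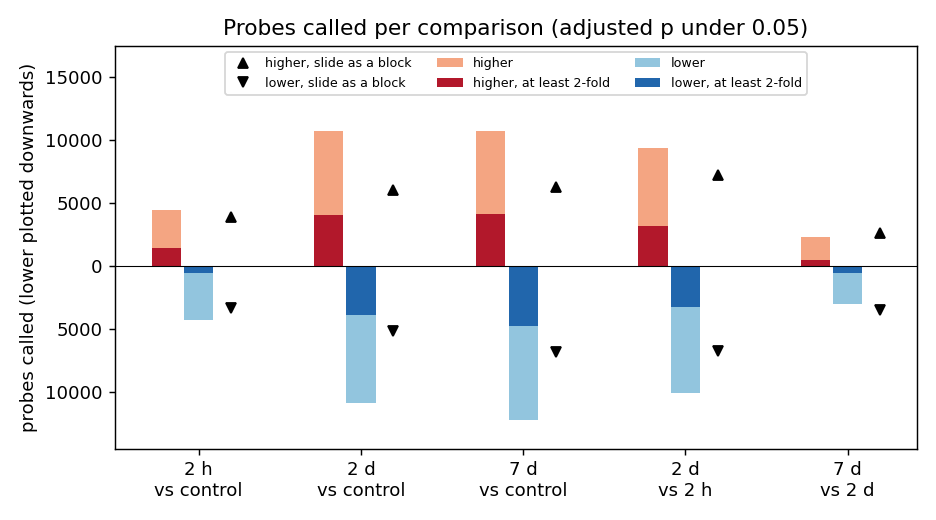
Probes called higher (upward bars) or lower (downward bars) at an adjusted p under 0.05 in each of 5 comparisons, with the part that changed at least 2-fold in the darker colour and triangles for the counts with the slide as a block. The y axis counts probes of 34439 tested; counts against control rise from 4457 higher and 4318 lower at 2 h to 10766 and 10883 at 2 d.

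At 7 d the counts against control were close to those at 2 d and depended on the slides in the same way. There were 10718 probes higher and 12203 lower, 66.6% of those tested, or 6324 and 6822 with the slide as a block, with 4171 at least 2-fold higher and 4720 at least 2-fold lower. RATLNCRNA_23424, which had risen at 2 d, stood at 3.16 ± 0.14 (SD, n = 3), 223-fold above control (log2 fold change 7.80, SE 0.25, limma adjusted p = 6.01e-09). RATLNCRNA_17802 (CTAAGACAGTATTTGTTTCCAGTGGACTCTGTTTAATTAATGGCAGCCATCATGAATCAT) climbed from -4.27 ± 0.39 in control to -2.41 ± 0.91 at 2 h, 1.56 ± 0.74 at 2 d and 3.25 ± 0.21 at 7 d, the last a log2 fold change of 7.51 (SE 0.43, limma adjusted p = 7.64e-08), or 5.95 under the slide block (limma adjusted p = 9.99e-05). RATLNCRNA_5871 (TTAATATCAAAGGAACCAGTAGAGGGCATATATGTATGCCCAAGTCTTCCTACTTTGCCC) went from 1.16 ± 0.08 to -2.51 ± 0.72 (log2 fold change -3.67, SE 0.42, limma adjusted p = 1.48e-05), or -2.60 under the slide block (limma adjusted p = 0.0152). RATLNCRNA_30146 (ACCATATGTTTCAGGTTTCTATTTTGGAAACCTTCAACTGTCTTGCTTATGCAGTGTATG) went from 1.14 ± 0.03 to a mean of -2.24, with pools from -3.97 to -1.30 (log2 fold change -3.38, SE 0.56, limma adjusted p = 0.000222), a call lost with the slide as a block (log2 fold change -2.75, limma adjusted p = 0.0596); without 7 d pool 2 its log2 fold change was -2.52. Under the normexp correction with quantile normalization, RATLNCRNA_23424 had 6.07, RATLNCRNA_17802 5.96 and RATLNCRNA_30146 -2.73. Fewer spots were well above background on the 7 d arrays (66.2% to 68.8%) than on the control arrays (74.6% to 81.4%), and the lowest signal that counted as well above background was higher on them, at 22.9 to 33.4 against 8.63 to 16.4 in control. There were 2488 probes well above background in all control pools and in no 7 d pool, of which 1435 were called lower, 168 with a fall of at least 2-fold and 0 of at least 8-fold by the bound. The reverse pattern held for 123 probes, all of them called higher with a rise of at least 2-fold by the bound. Without the filter on dim probes the directions turned, with 15313 probes higher and 12534 lower. No slide held both groups.

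The courses over the 3 times depended on how the slides are treated. Without a slide term, 7107 probes (20.6%) were called against control at no time, 7604 were not called at 2 h and lower at 2 d and 7 d, and 5663 were not called at 2 h and higher at 2 d and 7 d. Under a slide block these courses held 16023 (46.5%), 3584 and 2996 probes, so that no call became the most frequent. The level was higher at all 3 times in 2504 probes and lower at all 3 in 1801, or in 1369 and 710 under the block. At 2 h and at no later time, 710 probes were called higher and 776 lower, or 1637 and 1578 under the block. The block widens the error at 2 d and 7 d more than at 2 h, so calls lost at the later times add to these courses. Probes called only at 2 h under the block need not have returned to control. Of the 4457 probes higher at 2 h, 3055 were higher at 2 d, against 1393 that independent lists of these sizes would share and 1872 that were higher at both times with the slide as a block, where independent lists would share 690. The excess was smaller for falls. Lower at 2 h and 2 d were 2190 probes against 1364.5, or 934 against 500 under the block. At 2 h and 7 d, 2666 were higher against 1387, and 2031 lower against 1530. Unchanged groups simulated 20 times against the same control pools shared 0, which is no yardstick for lists of this length, since groups without change yield hardly any calls. At 2 d and 7 d together, 8899 probes were higher and 9642 lower, against 3351 and 3856 for independent lists. With the slide as a block the counts were 4762 and 4378, against 1114 and 1019. All 2 d and 7 d pools lay on slide 2 and all control pools on slide 1, so part of each excess may come from the shared control pools, which are too few to split, and part from the slides. Across probes, which are not independent replicates, the log2 fold changes at 2 h and 2 d had r = 0.463 and a covariance of 0.282, and the unchanged groups gave 0.502 and 0.0239. At 2 d and 7 d, r was 0.914 and the covariance 0.987, and the unchanged groups gave 0.502 and 0.0239.

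The step from 2 h to 2 d was compared directly. At 2 d, 9383 probes were higher and 10110 lower than at 2 h. Of the 4457 probes higher than control at 2 h, 1719 fell between 2 h and 2 d and 1001 rose further. Of the 4318 probes lower than control at 2 h, 2047 rose and 803 fell further. The 2 h pools served both to choose these probes and in the comparison with 2 d. The choice by itself therefore favours moves back toward control, and these counts do not measure a return. RATLNCRNA_864 (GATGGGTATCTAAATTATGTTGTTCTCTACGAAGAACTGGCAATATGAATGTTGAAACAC) was not well above background in any control pool, reached 3.64 ± 0.32 (SD, n = 3) at 2 h, at least 719-fold over control, and came down to -1.57 ± 0.17 at 2 d, still at least 19.4-fold over control and at 7 d at least 5.90-fold (log2 fold change from 2 h -5.21, SE 0.48, limma adjusted p = 3.85e-06). RATLNCRNA_859 (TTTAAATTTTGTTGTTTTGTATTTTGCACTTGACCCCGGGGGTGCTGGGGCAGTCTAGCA) also peaked at 2 h, from -3.90 ± 0.20 in control to 2.18 ± 0.27 at 2 h and -2.90 ± 0.37 at 2 d. Its log2 fold change from 2 h was -5.08 (SE 0.21, limma adjusted p = 1.19e-08), or -4.40 under the normexp correction. It was still called above control at 2 d (limma adjusted p = 0.00122) and at 7 d (log2 fold change 0.54, limma adjusted p = 0.0367). Both of these comparisons with control cross the slides, so a part from the slides stays open. Among probes measured on every array of both groups, the largest rises were those of RATLNCRNA_7987 (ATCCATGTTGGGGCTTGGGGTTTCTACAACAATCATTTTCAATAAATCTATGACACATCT) and RATLNCRNA_34842 (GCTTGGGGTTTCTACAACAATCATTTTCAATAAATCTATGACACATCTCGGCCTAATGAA), which share 48 nt on the same strand. RATLNCRNA_7987 went from -0.84 ± 0.09 at 2 h to 4.94 ± 0.27 at 2 d (log2 fold change 5.78, SE 0.23, limma adjusted p = 1.03e-08), and RATLNCRNA_34842 from -1.53 ± 0.19 to 4.24 ± 0.37 (log2 fold change 5.77, SE 0.24, limma adjusted p = 1.33e-08). A slide block in the fit gave 7264 probes higher and 6755 lower. Within slide 2, where 2 h pool 3 stood alone and was assumed to vary like the other pools, 5474 were higher and 3988 lower.

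**Figure D3:**
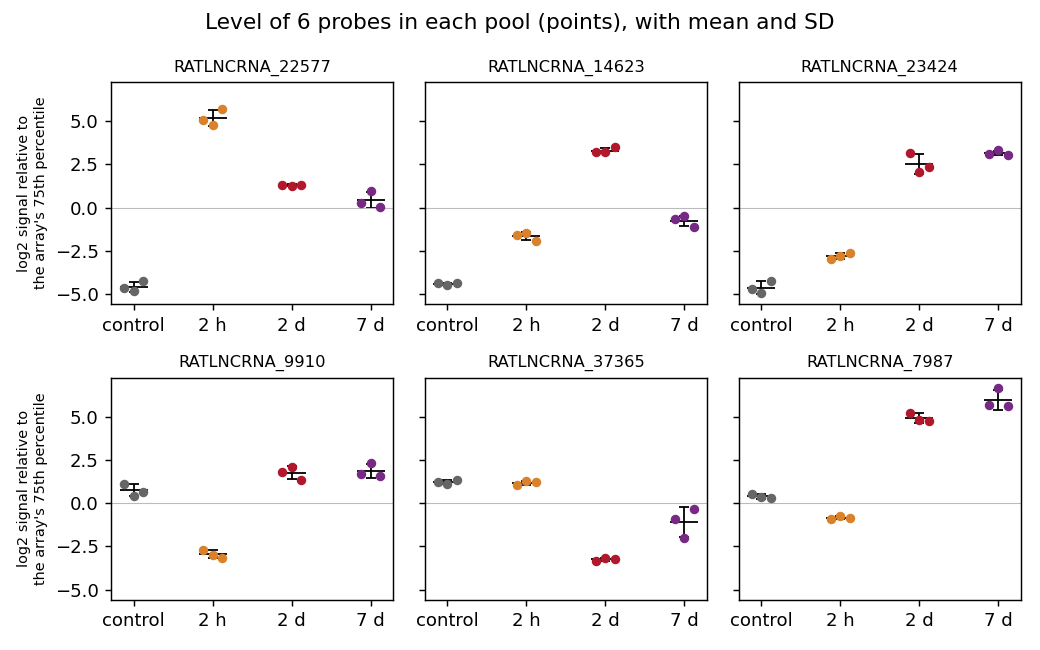
Level of 6 probes in each pool (points), with the mean and SD of each group of 3 pools (bars); the y axis is the log2 signal relative to the 75th percentile of the array and the x axis the group. RATLNCRNA_22577 peaked at 2 h with 5.20, RATLNCRNA_14623 at 2 d with 3.30, and RATLNCRNA_23424 stayed high at 7 d with 3.16, while RATLNCRNA_9910 was lowest at 2 h with -2.95.

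Between 2 d and 7 d the change was smaller, and here all 6 arrays lay on slide 2. At 7 d, 2297 probes were higher and 3012 lower than at 2 d, 15.4% of those tested, with 487 at least 2-fold higher and 521 at least 2-fold lower. Of the 10766 probes higher than control at 2 d, 1576 fell and 1017 rose further by 7 d. Of the 10883 probes lower than control at 2 d, 680 rose and 510 fell further. Here too the 2 d pools served both for the choice and for the comparison, which favours moves back toward control. RATLNCRNA_14623, which had the largest rise at 2 d among probes measured on every array of both groups, came down from 3.30 ± 0.16 to -0.77 ± 0.31 (SD, n = 3; log2 fold change -4.07, SE 0.16, limma adjusted p = 2.84e-07). RATLNCRNA_16584 (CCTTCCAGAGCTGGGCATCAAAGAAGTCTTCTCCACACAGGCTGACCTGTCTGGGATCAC), not well above background in any control pool, went from -0.27 ± 0.30 at 2 d to -4.05 ± 0.35 at 7 d (log2 fold change -3.78, SE 0.26, limma adjusted p = 8.84e-06). RATLNCRNA_9029 (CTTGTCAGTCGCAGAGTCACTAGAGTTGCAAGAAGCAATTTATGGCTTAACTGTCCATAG) rose from -4.49 ± 0.47 to -0.63 ± 0.11 (log2 fold change 3.86, SE 0.46, limma adjusted p = 0.000255). RATLNCRNA_27573 (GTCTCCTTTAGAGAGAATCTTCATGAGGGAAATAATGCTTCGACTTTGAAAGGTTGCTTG) rose from -3.59 ± 0.67 to 0.25 ± 1.93 (log2 fold change 3.84, SE 0.71, limma adjusted p = 0.00393), with the 7 d pools at -0.67, 2.47 and -1.05. Its log2 fold change was 2.73 without 7 d pool 2 and 4.49 without 7 d pool 3. The normexp correction with quantile normalization gave -2.63 for RATLNCRNA_16584, 2.56 for RATLNCRNA_9029 and 2.84 for RATLNCRNA_27573. With the slide as a block in the fit of all arrays, 2621 probes were higher and 3454 lower, and the arrays of slide 2 alone gave 1078 and 1472. Since both groups lay on slide 2, these settings left the fold changes as they were and altered only the error. The counts fell to 1246 and 1898 without 2 d pool 2 and to 1283 and 1859 without 2 d pool 3.

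Probes that overlap in sequence measured nearly the same stretch of a strand. There were 1247 pairs of probes, each in a single pair, that shared at least 25 nt on the same strand. The median was 54 shared nt of 60, so most pairs come close to duplicate spots of a probe. Across these pairs, which are not independent replicates, the log2 fold changes correlated with r between 0.876 and 0.963 over the 5 comparisons. At 2 d against control both members were called in 798 pairs, in the same direction in 793 and in opposite directions in 5. In 95 pairs the probes matched opposite strands over at least 25 nt, and both were called in 11 of these at 2 h, 36 at 2 d and 38 at 7 d against control. They went in the same direction in 9, 18 and 25 pairs and in opposite directions in 2, 18 and 13.

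**Figure D4:**
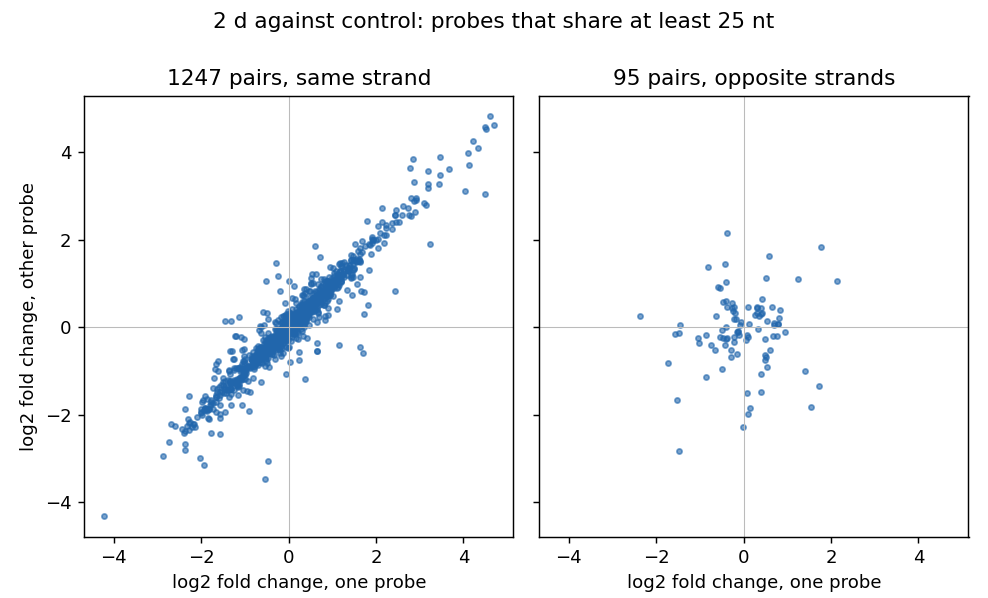
Log2 fold change of 2 d against control for the members of 1247 pairs of probes that share at least 25 nt on the same strand (left) and 95 pairs on opposite strands (right), with a point for each pair and a member on each axis. Same-strand pairs follow the diagonal (r = 0.954), and opposite-strand pairs had r = 0.109.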

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

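The tests of the pools that stood apart, the repeat of the slide test with other reference pools, the sets of opposite sign with the slide as a block and the fits without those pools were chosen after the result was seen, and the other tests before. Effects of opposite sign at different times, with the direct difference between the times also called, marked 4 sets of probes for a closer look. The direct difference was called for every probe with called effects of opposite sign. That condition therefore removed no probe and adds no separate support. There were 277 probes higher than control at 2 h and lower than control at 2 d, and 851 with the reverse course. From 2 d to 7 d, 127 probes went from higher than control to lower, and 56 from lower to higher. With the slide as a block, 84 of the 277, 400 of the 851, 12 of the 127 and 3 of the 56 met the same conditions. The wider error under the block lowers such counts with or without a slide difference. Among named probes, RATLNCRNA_9910 and RATLNCRNA_18459 were below control at 2 h and above it at 2 d, with log2 fold changes of 2 d against 2 h of 4.72 and 4.79. RATLNCRNA_7987 and RATLNCRNA_34842, which overlap in sequence and so are not separate cases, did likewise, with 5.78 and 5.77.

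Over 60% of the probes were called at 2 d and 7 d against control, in comparisons that cross the slides; a GC trend as the whole cause is argued against by its small correlation with the fold changes at 2 d (r = 0.0181 across probes) and by its removal together with that of mean level, which left 95.5% of the 7913 probes changed at least 2-fold at 2 d with such a change. For the slide, the difference between 2 h pool 3 and the 2 h pools on the other slide served as an estimate, and 9.14% of those probes had an estimate of the same sign and at least 0.5 times the size, just under the limit of 10% set beforehand for a slide difference to be ruled out as the main cause. By that limit alone a slide difference would have been argued against; a stricter reading was adopted after the value was seen, because the estimate rests on a single array, which also had the dimmest spike-in signal (11.2 against 11.6 to 12.2 on the log2 scale), and set against 2 h pool 1 alone the share was 9.97%. Under it, the slide and the time after injury cannot be told apart for the full set. A part from the slide stays open: 69.0% of those probes had an estimate of the same sign, and the estimate correlated with the fold changes at 2 d (r = 0.301 across probes) but hardly with 7 d against 2 d (r = 0.0153). However, 2 h pool 3 lay at -63.8 on the first component, against -83.7 and -82.2 for 2 h pools 1 and 2. On the second it lay at 71.7, against 47.9 and 51.6. A pool that differed more from control would give the same pattern, and the estimate cannot tell this from a slide difference. Spike-in RNA, which does not depend on the tissue, did respond differently by slide. Its slope of signal on amount was 1.06 in 2 h pool 3, against 0.958 and 0.941 in 2 h pools 1 and 2. How far this difference enters the fold changes of the probes was not tested.

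Pool 1 at 2 d and pool 2 at 7 d lay further from control than the other pools of their groups. The array of 7 d pool 2 was the dimmest of the 12 (75th percentile of the signal 496, against 593 to 749 on the others). That of 2 d pool 1 was not dim (742). The excess was not confined to dim probes. Among the brightest probes the slope of the pool's deviation on its group's effect was 1.13 times the slope over all probes in 7 d pool 2. In 2 d pool 1 it was 0.926 times. The group's effect contains the pool, and this ratio lay between 0.807 and 1.17 in all 2 d and 7 d pools. It therefore does not settle whether low signal played a part in 7 d pool 2. On the effect of the other time point, the deviations of 2 d pool 1 had slopes of 0.123 for probes that rose and 0.224 for probes that fell, and those of 7 d pool 2 had 0.149 and 0.541, so the falls were stronger. The pools were picked along an axis that both times share (r = 0.914 between their effects across probes), so a positive slope was built in and does not bear on the cause, which stays open, and no biological explanation was tested. Without both pools the counts stayed within 1.5 times those of all arrays, with 9678 probes higher and 12036 lower at 7 d against control.

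For each comparison the 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. In fits of those 6 arrays the real split called 11326 probes for 2 h against control and the highest of the other splits 1. The real split called 23584 for 2 d against control, 22835 for 7 d against control, 18596 for 2 d against 2 h and 2579 for 7 d against 2 d, with 0 in the highest other split of each. In each comparison 1 of the 10 splits, the real one, gave as many. Every other split has arrays of both groups on both sides, so a group difference enters the spread and leaves few calls. The other splits are therefore no measure of the calls that unchanged groups would give.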

How the results depend on the processing

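The fits without the pools farthest along the first component, those within slide 2 for 2 d against 2 h and the shared calls and courses with the slide as a block were added after the data were seen. Signal over background limits falls more than rises, since a probe cannot be followed below background. Replicate numbers did not pair the pools: 2 of 18 same-numbered pairs of arrays deviated together with r over 0.1, and 3 of 12 arrays correlated best with an array of their own number. With the replicate block 1839 probes were higher and 2403 lower at 7 d against 2 d, and 4096 and 3644 at 2 h against control, within 1.5 times the counts without it, as were the other comparisons. Counts under other normalizations, the authors' table, other filters, kept flags, no variance trend and the slide as a random block also stayed within 1.5 times. The balance of directions was less stable: median centring gave 3816 higher and 5385 lower at 2 h, and no filter 15313 and 12534 at 7 d. With the slide as a fixed block, the counts for 2 d against control moved to 6069 higher and 5144 lower and those for 7 d to 6324 and 6822. The block widens the error of both comparisons, which lowers counts by itself. Within slide 1 the lower count at 2 h rose to 7365. Within slide 2, 2 d against 2 h gave 5474 and 3988 with a lone 2 h pool, and 7 d against 2 d gave 1078 and 1472; the 6 arrays of 2 d and 7 d alone gave 1091 and 1488. The fewer arrays and degrees of freedom are part of these settings, but counts moved both ways. The 6 arrays of 2 h and control alone gave more calls than all 12, 5044 higher and 6282 lower. Fits of fewer groups also take the variance from those groups only. The median SD between pools was 0.09 in control, 0.15 at 2 h, 0.13 at 2 d and 0.17 at 7 d. Beyond that the cause was not tested. At an adjusted p under 0.01, 2882 probes were higher and 2191 lower at 2 h against control, and 992 and 1355 at 7 d against 2 d. Requiring a change of at least 2-fold left 1438 higher and 524 lower at 2 h, 4044 and 3869 at 2 d and 4171 and 4720 at 7 d against control, 3223 and 3259 for 2 d against 2 h, and 487 and 521 for 7 d against 2 d. Shared calls under that threshold were 896 higher and 116 lower at 2 h and 2 d, 746 and 97 at 2 h and 7 d, and 3182 and 3358 at 2 d and 7 d. With the slide as a block and no limit on the fold change, shared calls were 1872 and 934, 1527 and 880, and 4762 and 4378. These are not comparable with the counts at 2-fold. Both stricter thresholds lower counts by construction. Leaving out each pool in turn gave 3369 to 4189 higher and 2691 to 3800 lower at 2 h, 9627 to 9977 and 9689 to 10251 at 2 d, and 9563 to 10592 and 11130 to 11752 at 7 d against control, 8234 to 9837 and 8444 to 10625 for 2 d against 2 h, and 1246 to 2331 and 1859 to 3290 for 7 d against 2 d. The named probes kept their direction and call in 120 of 120 fits without a pool and in 99 of 100 other fits. The exception was RATLNCRNA_30146 at 7 d with the slide as a block (log2 fold change -2.75, limma adjusted p = 0.0596). Named probes had been chosen for groups whose arrays do not overlap, so leaving out a pool could not turn their direction. The replicate block, and the slide block for 7 d against 2 d, cannot alter fold changes by design. In those fits only the call was open. The sizes of the fold changes moved more. Background correction with an offset, which shrinks folds of dim signals by construction, was run together with quantile normalization. This setting took RATLNCRNA_22577 at 2 h from 9.80 to 8.17, RATLNCRNA_14623 at 2 d from 7.73 to 6.11 and RATLNCRNA_23424 at 7 d from 7.80 to 6.07. Quantile normalization alone gave 9.79, 7.66 and 7.75. The planned gene list, noncoding gene and probe-choice alternatives were not run, since the files give no gene names.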

Other observations

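The hypotheses in this part and the limits for them were set before their results were seen. The p-values for the pairs, their adjustment and the larger number of re-pairings were added after the first correlations were seen, and the rank of the motif in other comparisons was noticed afterwards. Probes on opposite strands of the same sequence bear on antisense transcription only if each probe reported its own strand, which was not tested. Over 95 such pairs, the log2 fold changes were compared with those of randomly re-paired probes, a family of 5 correlations across pairs. The permutation p-values take pairs as units, so they do not measure the spread between pools or animals. At 2 h against control r was 0.367 (one-sided permutation p = 0.00012, adjusted p = 0.0006), at 7 d against control 0.236 (permutation p = 0.0109, adjusted p = 0.0181) and at 7 d against 2 d 0.279 (permutation p = 0.00531, adjusted p = 0.0133). At 2 d against control r was 0.109 (permutation p = 0.146, adjusted p = 0.146) and at 2 d against 2 h 0.116 (permutation p = 0.131, adjusted p = 0.146), inside the range of re-paired probes. A tendency of probes on opposite strands to change together may therefore exist, but the times were not tested against each other. Whether 2 transcripts or 1 lie behind such a pair cannot be told from these values. The 95% intervals of r from resampled pairs overlapped, with 0.125 to 0.570 at 2 h, -0.148 to 0.342 at 2 d and -0.00865 to 0.447 at 7 d against control. Same-strand pairs had r of 0.876 to 0.963, but they shared a median of 54 nt, against 42 for opposite strands. Of the pairs with both members called, 2 moved apart at 2 h, 18 at 2 d and 13 at 7 d against control, and 9, 18 and 25 moved together.

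A second hypothesis was that probes holding TATTTAT, a core of the AU-rich elements found in short-lived messenger RNAs, rise 2 h after injury. The 399 such probes had a mean shift of 0.06 (SE 0.04, log2) at 2 h against control, after removal of GC and mean-level differences, a shift within 2 SE of 0. The motif ranked 4 among the 21 orders of its bases and 297 of 8146 heptamers, so base composition alone could give a shift of this size. The reverse complement ATAAATA shifted by -0.00946 (SE 0.03), which is too near the error of both to tell a strand-specific effect from none. The hypothesis was thus not borne out at 2 h. In 2 d against 2 h the same probes had a mean shift of -0.17 (SE 0.05), rank 4 from the lowest of 8146 heptamers and lowest of the 21 orders; this was seen while scanning 8146 heptamers in 5 comparisons and is a value to test in other data.

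Spike-in RNA, which is added in known amounts, was dimmer on 1 array: 7 spike-in probes averaged 11.2 on the log2 scale in 2 h pool 3 and between 11.6 and 12.2 in the other pools. The slope of spike-in signal on amount lay between 0.941 and 0.959 on slide 1 and between 1.03 and 1.06 on slide 2. Without 2 h pool 3, 3910 probes were higher and 3360 lower at 2 h against control.

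Probes with a poly(A) signal hexamer, AATAAA or ATTAAA, made up 22.4% of those tested. At 2 h against control 17.3% of them were lower, against 11.2% of the other probes, while the shares that were higher were nearly equal (12.9% of those with the hexamer). At 2 d against control they were called more often in both directions, with 35.6% higher and 34.6% lower, each a larger share than among the other probes, and at 2 d against 2 h 33.3% were higher, against 25.5%. They were also brighter, with a median level of 0.32 against -1.82, so the classes differ in level as well as in sequence, and neither the differences between the classes nor their cause was tested.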
